A study of Homo sapiens with 12 samples.

How the data were processed

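RNA sequencing was done on 12 libraries from COV362 and PEO1, 2 established human lines of high-grade serous ovarian carcinoma. Each line was given DMSO vehicle or 20 nM prexasertib, an inhibitor of the checkpoint kinases CHK1 and CHK2. The 4 groups held 3 replicates each, lettered A, B and C. The treatment time is not given in the labels. Nothing in the labels says whether the replicates are separate cultures, so every p-value measures only the spread between these samples. Per the labels' protocols, total RNA was extracted on columns and made into libraries with the TruSeq RNA Library Prep Kit v2, which selects polyadenylated RNA and does not keep the strand.

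Per the submitters' processing notes, STAR and featureCounts 1.4.6 of the Subread package were used with genome build hg38. The role and order of the tools are not given. The deposited values are raw counts per gene for each library, with no normalization, in a table of 26485 genes with exon coordinates, strand and total exon length in bases per the file headers. Gene positions are taken from that table as the start and end of the outermost exons. Its names include 28 that a spreadsheet had turned into dates, and those genes carry no usable symbol. Of the tested genes, 465 are listed on several chromosomes or sequences, and no position is given for them. Because the kit is unstranded, reads from overlapping genes on opposite strands cannot be assigned with certainty. Counts of near-identical copies, such as the histone and HLA genes, are likewise uncertain, since the handling of reads with several matches is not stated.

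Library totals ranged from 9390790 (COV362 DMSO A) to 18262805 (COV362 DMSO B). The PEO1 libraries held 15541151 to 18260493 counts. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14498, while 5652 genes had 0 counts in every library. Scaling factors were computed by the trimmed mean of M-values (TMM). Counts scaled to the library size with these factors (CPM) are given as group means with the standard deviation (SD) over 3 libraries.

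Differences were tested in edgeR 4.0.16 under R 4.3.3 with a quasi-likelihood F-test (QL) on 1 fit of 4 group means to 12 libraries, with 8 residual degrees of freedom. The comparisons were 4: prexasertib against DMSO in COV362, the same in PEO1, the difference between these changes, and PEO1 DMSO against COV362 DMSO. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 over all tested genes. Errors of log2 fold changes are standard errors (SE) from that fit. A fold against a group with 0 counts in all its libraries is given as a lower bound, computed against a floor of 3 counts over the group, and such a floor covers counting error only.

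Gene lists were fixed before the data were examined, as were the comparisons, the thresholds, the rule for named genes and most alternatives. There were 32 lists of 718 genes, 705 of them in the table. The core lists, 12 in number, covered the ATR and CHK1 checkpoint, E2F targets and DNA replication, G2/M and mitosis, homologous recombination and Fanconi anemia genes, p53 targets, the interferon response, inflammatory NF-κB targets, AP-1 and immediate early genes, apoptosis, the ATF4 and unfolded protein response, epithelial-mesenchymal transition with matrix genes, and epithelial genes. The other lists covered further pathways and cell type markers. Lists with at least 3 tested genes, 30 in all, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. The preset test treats the genes of a list as nearly independent, so each list call, and each one gained with the block, is given with its p-value from the estimated correlation. No such p-value was computed for the length and GC correction or without the A libraries. Counts of called list members are given over all tested genes and, in those words, adjusted over the list alone.

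Genes were named by a fixed rule. For each drug comparison it took the 6 highest and the 6 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the line, every treated library beyond every DMSO library, and a named symbol. It added the 2 members with the largest absolute change among called members with a mean of at least 1 CPM in each core list, or the member with the lowest p where no member was called. The same was done for other lists whose camera test passed. CHEK1, CHEK2, WEE1, CDC25A, CDKN1A, CCNE1, MKI67, IFNB1 and CXCL10 were always included. For the difference between the lines it took the 5 highest, the 5 lowest and up to 4 genes called in opposite directions, and for the DMSO comparison the 3 highest and the 3 lowest. Some genes that the rule takes are not reported here. Other genes are named as members of these lists, and their choice as examples was made after their values were seen.

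The lines' letters were checked for pairing by correlating each library's deviation from its group mean between DMSO and treated libraries with the same letter, with a threshold of 0.1. In COV362 the values were 0.41, 0.42 and 0.13 for A, B and C, so results with the letter as a block are given beside the COV362 results where they change a call or move a count by over 1.5 times. In PEO1 they were 0.30, 0.17 and 0.08, so that the letters were not taken as pairs there. The method was tested on simulated data with 50 genes changed at each fold. Each gene had 1 spread, estimated from all 12 libraries, and no effect of the letter was simulated. The shares below are thus not those of each line's own spread. In COV362, 42% of the genes changed 2-fold and 76% of those changed 4-fold were called, with 5 false calls. In PEO1 these shares were 56% and 84% with 12 false calls, and for the difference 28% and 64% with 3 false calls. A simulated list changed by 1.5-fold was called in both lines, with 0 other lists called among 30 by camera. Those lists held random genes simulated independently, so this cannot show how often camera calls lists of correlated genes falsely.

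Alternatives were scaling by relative log expression (RLE) or the upper quartile, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries of a comparison alone, the replicate letter as a block, a minimum fold of 1.5 (glmTreat), an adjusted p under 0.01, and leaving out each library. A further 4 alternatives were chosen after seeing the data: a correction of each library's trend with exon length and GC content (splines with 5 degrees of freedom, pseudocount 0.5, GC values for 94.5% of tested genes), that correction with the block, the block with an estimated correlation for the lists, and leaving out the 4 A libraries together. Splits of the samples, thinning of counts and tests of technical explanations are given in the closing observations. Figures were drawn with matplotlib 3.10.9. Mitochondrially encoded genes are not listed in the table, and none of the 13 in their list could be tested. The erythroid list had no member with enough counts. Sequence variants were not analysed here.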

Results

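The design asked how 20 nM prexasertib changed transcript levels in the ovarian carcinoma lines COV362 and PEO1, and whether the lines responded alike. Log2 CPM values correlated within groups at 0.968 to 0.986 (COV362 DMSO), 0.959 to 0.984 (COV362 prexasertib). In PEO1 the ranges were 0.983 to 0.989 (PEO1 DMSO) and 0.980 to 0.989 (PEO1 prexasertib). Between lines they were 0.760 to 0.814. The first principal component held 77.8% of the variance and parted the lines. The second, with 8.51%, parted the PEO1 DMSO libraries (41.4 to 56.5) from the treated ones (−50.4 to −39.3). The letter of the replicate left a trace as well. Counts in the A libraries leaned toward short genes (rho with exon length −0.41 and −0.37 in COV362 DMSO and prexasertib, −0.36 and −0.35 in PEO1), and in the B libraries toward long ones (0.44 and 0.37, 0.13 and 0.41). The C libraries were at 0.09 and 0.11 in COV362 and at 0.32 and −0.05 in PEO1, where the letters thus showed no common order in exon length beyond A. With GC content, the B libraries had the lowest rho in every group (−0.43 and −0.57 in COV362 DMSO and prexasertib, −0.39 and −0.38 in PEO1). Unless stated otherwise, adjusted p-values are from edgeR's QL test for genes and camera for lists, both BH-adjusted, with n = 3 libraries per group.

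In COV362 cells, prexasertib raised transcripts of immediate early, inflammatory, interferon-induced and histone genes. EGR1, an immediate early transcription factor (chromosome 5, 138465492 to 138469315), rose from 1.51 ± 0.998 to 25.6 ± 0.545 CPM, a log2 fold change of 3.94 ± 0.32 (edgeR QL, BH-adjusted p = 6.16e-05). ATF3, a stress-induced transcription factor (chromosome 1, 212565334 to 212620777), rose from 13.6 ± 2.23 to 92.9 ± 6.09 CPM (2.78 ± 0.16 on the log2 scale, edgeR QL, BH-adjusted p = 1.60e-06). CDH6, which encodes a cadherin of cell-cell adhesion (chromosome 5, 31193655 to 31329146), fell from 380 ± 66.0 to 151 ± 12.6 CPM (−1.33 ± 0.14, edgeR QL, BH-adjusted p = 0.000778). Among called genes with a symbol, a mean of at least 5 CPM in the line and groups that did not overlap, the other highest risers were the cytokine gene IL11 (6.47-fold, log2 2.69 ± 0.32), the neutrophil chemokine gene CXCL8 (4.52-fold, 2.18 ± 0.25) and the histone genes HIST1H2BD (4.27-fold, 2.09 ± 0.29) and HIST1H1C (3.69-fold, 1.88 ± 0.27). Their edgeR QL, BH-adjusted p-values were 0.00198, 0.00145, 0.00442 and 0.00442. Under the same limits the other largest falls were in TMEM100, a membrane protein gene (−2.49 ± 0.43, from 90.6 ± 37.4 to 16.2 ± 9.05 CPM), CLIC5 (−1.83 ± 0.39), the neuronal microtubule protein gene MAP2 (−1.44 ± 0.30), the keratin gene KRT4 (−1.37 ± 0.28) and the epithelial transcription factor gene EHF (−1.37 ± 0.23). Their edgeR QL, BH-adjusted p-values were 0.0207, 0.0466, 0.0436, 0.0350 and 0.0106. In total 120 genes were called, 88 higher and 32 lower. Of these 59 and 16 changed at least 2-fold.

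Of 29 AP-1 and immediate early genes tested in COV362, 7 rose and 0 fell (14 and 0 adjusted over the list alone; 15 and 0 at an unadjusted p under 0.05; DESeq2 9 and 0, limma-voom 5 and 0). Besides EGR1 and ATF3 these were DUSP1, FOS, FOSB, HBEGF and KLF4, with FOS at 1.70 on the log2 scale. The list's median was 0.61 (camera, BH-adjusted p = 4.95e-16; adjusted p = 0.0389 with an estimated correlation). Of 25 inflammatory NF-κB targets 7 rose and 0 fell (12 and 0 adjusted over the list alone; 13 and 0 at an unadjusted p under 0.05; DESeq2 11 and 0, limma-voom 6 and 0). Among them were CXCL8, the signalling adaptor gene TRAF1 (1.66 ± 0.29, from 4.74 to 15.4 CPM, edgeR QL, BH-adjusted p = 0.0161), ICAM1 at 1.52 and IL6 at 1.28. Their median was 0.89 (camera, BH-adjusted p = 5.49e-13; adjusted p = 0.0389 with an estimated correlation). Of 32 interferon response genes 5 rose and 0 fell (14 and 0 adjusted over the list alone; 18 and 0 at an unadjusted p under 0.05; DESeq2 12 and 0, limma-voom 4 and 0). These were IRF7, a regulator of interferon transcription (1.80 ± 0.38), MX1, an antiviral GTPase gene (1.25 ± 0.20, from 23.7 to 56.7 CPM), IFIT2, IFIT3 and OASL. The list's median was 0.61 (camera, BH-adjusted p = 4.95e-16; adjusted p = 0.0415 with an estimated correlation). Of 17 replication-dependent histone genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; 9 and 0 at an unadjusted p under 0.05; DESeq2 9 and 0, limma-voom 8 and 0). Their median was 1.63 (camera, BH-adjusted p = 1.50e-12; adjusted p = 0.0389 with an estimated correlation). The largest of these were HIST1H2BG, from 0.244 to 2.46 CPM (3.32 ± 0.41), and HIST1H4H, from 0.487 to 4.75 CPM (3.14 ± 0.43). Their edgeR QL, BH-adjusted p-values were 0.00230 and 0.00442. With the replicate block alone, edgeR called 19 AP-1, 14 NF-κB, 20 interferon and 9 histone genes higher, and 0 lower in each list. With the replicate block and an estimated correlation together, camera called none of these 4 lists (BH-adjusted p = 0.121 for AP-1, 0.0881 for NF-κB, 0.121 for interferon and 0.0881 for histone genes) and none of the other lists in COV362.

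In COV362 the p53 target CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 6.76 ± 1.89 to 20.1 ± 1.62 CPM (1.55 ± 0.23, edgeR QL, BH-adjusted p = 0.00559). GADD45A, a DNA damage-induced gene, rose 2.35-fold (1.23 ± 0.16, adjusted p = 0.00318). These were the 2 of 28 p53 targets called (5 higher and 2 lower adjusted over the list alone). The list's median was 0.17 (camera, BH-adjusted p = 0.00833; adjusted p = 0.0811 with an estimated correlation). Of 27 ATF4 and unfolded protein response genes 3 rose: PPP1R15A, which restores translation after stress (1.47 ± 0.17, adjusted p = 0.00145), DDIT3, which encodes CHOP (1.27 ± 0.25, adjusted p = 0.0295), and the amino acid transporter gene SLC3A2 (0.68). Adjusted over the list alone there were 6 higher and 0 lower. The list's median was 0.22 (camera, BH-adjusted p = 0.000306; adjusted p = 0.0811 with an estimated correlation). Of 23 lysosome and autophagy genes 4 rose (5 adjusted over the list alone), SQSTM1 by 0.82 ± 0.13 and MAP1LC3B by 0.72 ± 0.14, with NEU1 and GABARAPL1. Their list's median was 0.09 (camera, BH-adjusted p = 0.00163; adjusted p = 0.107 with an estimated correlation). Among 16 genes of the MHC class I list HLA-B rose by 0.69 ± 0.14 on the log2 scale, 1 called gene both over all genes and adjusted over the list alone. The median of that list was 0.29 (camera, BH-adjusted p = 0.00214, or 0.0614 without COV362 prexasertib C; adjusted p = 0.107 with an estimated correlation). The ovarian lineage list of 12 genes was lower (median −0.39, camera, BH-adjusted p = 0.0173; 0.0503 without DMSO A and 0.0724 without prexasertib B; adjusted p = 0.0811 with an estimated correlation). The retinoid-binding gene CRABP2, its 1 called member without the block, rose by 1.05 even so (1 higher and 2 lower adjusted over the list alone). With the block edgeR called 1 member of this list higher and 7 lower. Of 3 tested immune markers, edgeR called 0 (2 higher adjusted over the list alone; 2 at an unadjusted p under 0.05; DESeq2 2, limma-voom 0). The median of the 3 was 0.53 (camera, BH-adjusted p = 0.0102; 0.0504 without DMSO A and 0.0516 with the length and GC correction; adjusted p = 0.121 with an estimated correlation). With the block edgeR called 2 of these markers higher and 0 lower. For p53 targets the block gave 6 higher and 3 lower, and for ATF4 and unfolded protein response genes 8 and 1. Lysosome and autophagy genes had 6 and 1 with it, and the MHC class I list 5 and 0.

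Genes of replication and recombination were lower as groups in COV362, while edgeR called no single member without the block. For 41 E2F and replication genes the median was −0.20 (camera, BH-adjusted p = 6.63e-05; adjusted p = 0.0428 with an estimated correlation, or 0.121 with the block as well). There were 2 lower adjusted over the list alone, 1 higher and 8 lower at an unadjusted p under 0.05, and 0 and 4 by DESeq2, 0 and 1 by limma-voom. The replicate block gave 1 higher and 10 lower members called by edgeR. For 35 homologous recombination and Fanconi anemia genes the median was −0.29 (camera, BH-adjusted p = 0.000214, fry 0.0549; adjusted p = 0.204 with an estimated correlation). There were 0 called in edgeR or adjusted over the list alone, 6 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. With the block 9 were lower, among them FANCC (−0.62 ± 0.16, adjusted p = 0.0963, with the block 0.00278). The checkpoint list of 22 genes (median −0.09, camera, BH-adjusted p = 0.231) also had 0 called in edgeR and adjusted over the list alone (1 higher and 5 lower at an unadjusted p under 0.05; DESeq2 0 and 1, limma-voom 0; block 1 and 5). RPA1, which coats single-stranded DNA, was at −0.37 ± 0.11 (adjusted p = 0.142, with the block 0.00126), and CHEK2, a target of the drug, at −0.53 ± 0.18 (0.204, with the block 0.0280). CHEK1, the main target, was at −0.17 ± 0.12 (adjusted p = 0.629), WEE1 at 0.11 ± 0.16 (0.863). The phosphatase gene CDC25A was at −0.17 ± 0.13 (0.664), the cyclin E1 gene CCNE1 at −0.24 ± 0.15 (0.567) and the proliferation marker MKI67 at −0.01 ± 0.18 (0.9998, or 0.12 with the length and GC correction, 0.643). With the block these 5 stayed uncalled, and only with block plus length and GC correction did CCNE1 pass (0.0227).

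The 35 G2/M and mitosis genes showed no shift in COV362 (median −0.04, camera, BH-adjusted p = 0.955). There were 0 called by edgeR and adjusted over the list alone, 2 higher and 3 lower at an unadjusted p under 0.05, 2 higher by DESeq2 and 0 by limma-voom. With the block 3 rose and 8 fell, CDC20, an activator of the anaphase-promoting complex, among the first (0.46 ± 0.13, edgeR QL, BH-adjusted p = 0.134, with the block 0.000123). Of 26 apoptosis genes 0 were called by edgeR and adjusted over the list alone (6 higher and 1 lower at an unadjusted p under 0.05; DESeq2 and limma-voom 0; block 4 and 2). The pro-apoptotic BCL2L11 was at 0.37 ± 0.13 (adjusted p = 0.213, with the block 0.0458), and the list at a median of 0.08 (camera, BH-adjusted p = 0.303). Of 30 transition and matrix genes edgeR called 0 (1 higher and 2 lower adjusted over the list alone; 4 and 2 at an unadjusted p under 0.05; DESeq2 1 and 2, limma-voom 0 and 1; block 4 and 5; median −0.07, camera, BH-adjusted p = 0.533). The matrix gene TNC was at −0.64 ± 0.15 (adjusted p = 0.0700, with the block 8.45e-07). Of 28 epithelial genes it called 0 (1 higher adjusted over the list alone; 3 and 1 at an unadjusted p under 0.05; DESeq2 1 and 0, limma-voom 0; block 4 and 1; median −0.06, camera, BH-adjusted p = 0.979, with the block higher at 0.678). The tight junction gene CLDN4 was at 0.64 ± 0.15 (adjusted p = 0.0710, with the block 0.000141). Limma-voom did not call CLIC5, MAP2 and IRF7, and IRF7 was not called without the A libraries. DESeq2 called FANCC, RPA1, CDC20, TNC and CLDN4 without a block. CXCL10, an interferon-induced chemokine gene, was at 0.71 ± 0.35 (adjusted p = 0.438), while IFNB1, which encodes interferon beta, was too low to test (0.0217 and 0.102 CPM).

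The size of the COV362 set depended on how the spread between letters was treated: 1977 genes were called with the block (832 higher and 1145 lower, all 120 kept), 533 by DESeq2 (300 and 233), 410 with the length and GC correction (206 and 204, 117 kept), 2123 with both (858 and 1265), 330 without the A libraries (184 and 146), 10 from the 6 COV362 libraries alone (with 7 of the 24 named genes called), 35 at an adjusted p under 0.01 and 16 against a 1.5-fold minimum. Leaving out 1 library gave 36 calls without DMSO B, 74 without DMSO C and 27 without prexasertib C, and of the 24 named genes called 20 stayed called without DMSO A (not CLIC5, KRT4, IRF7 and HLA-B), 14 without DMSO B (not TMEM100, CLIC5, MAP2, KRT4, EHF, IRF7, DDIT3, HLA-B, SQSTM1 and MAP1LC3B), 19 without DMSO C (not KRT4, IRF7, TRAF1, DDIT3 and MAP1LC3B), 20 without prexasertib A (not MAP2, IRF7, DDIT3 and MAP1LC3B), 18 without prexasertib B (not TMEM100, CLIC5, MAP2, KRT4, HLA-B and MAP1LC3B) and 12 without prexasertib C (not TMEM100, CLIC5, MAP2, KRT4, EHF, IRF7, MX1, TRAF1, DDIT3, HLA-B, SQSTM1 and MAP1LC3B).

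More genes were called in PEO1 than in COV362, with steep rises in single inflammatory and immediate early genes and falls in single adhesion and keratin genes. CXCL8 rose from 16.3 ± 4.88 to 589 ± 70.2 CPM (36.1-fold, log2 5.17 ± 0.27, edgeR QL, BH-adjusted p = 4.73e-08; chromosome 4, 73740506 to 73743716). The matrix metalloproteinase gene MMP3 (chromosome 11, 102835797 to 102843611) rose from 0.683 ± 0.258 to 28.3 ± 1.02 CPM (5.37 ± 0.47, edgeR QL, BH-adjusted p = 5.64e-06). CDH6 fell from 21.4 ± 1.60 to 2.03 ± 0.206 CPM (−3.40 ± 0.17, edgeR QL, BH-adjusted p = 4.33e-08). IGFBP5, which encodes a binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695549), fell from 465 ± 36.8 to 72.4 ± 5.54 CPM (−2.68 ± 0.17, adjusted p = 3.25e-07). Under the limits given for COV362, the highest log2 changes also included the axonemal dynein gene DNAH3 (7.10 ± 0.75, from 0.0983 to 14.3 CPM), the T-cell chemokine gene CCL5 (5.58 ± 0.51), the monoamine oxidase gene MAOA (5.58 ± 0.44) and RAET1L, a gene for a ligand of the NKG2D receptor (5.51 ± 0.43). Their edgeR QL, BH-adjusted p-values were 2.48e-05, 7.62e-06, 2.71e-06 and 2.46e-06. Under these limits the lowest also included the uroplakin gene UPK1B (−3.02 ± 0.39), the proteoglycan gene BGN (−2.75 ± 0.27), the keratin gene KRT15 (−2.72 ± 0.25) and the transglutaminase gene TGM1 (−2.57 ± 0.23). Their edgeR QL, BH-adjusted p-values were 0.000428, 1.46e-05, 9.11e-06 and 7.71e-06. In total 4249 genes were called, 29.3% of those tested, 2136 higher and 2113 lower. Of these 969 and 726 changed at least 2-fold.

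In PEO1, 19 of 29 AP-1 and immediate early genes rose and 0 fell (20 and 1 adjusted over the list alone; 1 lower at an unadjusted p under 0.05, by DESeq2 and by limma-voom). They included ATF3 (13.5 ± 1.49 to 224 ± 34.0 CPM, log2 4.05 ± 0.17), FOS, a subunit of AP-1 (2.73 to 38.0 CPM, 3.79 ± 0.24), EGR1 (2.82 ± 0.28) and DUSP1 at 2.31. Their median was 0.81 (camera, BH-adjusted p = 2.69e-07; adjusted p = 0.126 with an estimated correlation). Of 25 inflammatory NF-κB targets 15 rose and 3 fell (16 and 3 adjusted over the list alone). CCL20, which encodes a chemokine, rose from 0.127 to 4.90 CPM (5.12 ± 0.57, edgeR QL, BH-adjusted p = 3.58e-05) and PTGS2 by 4.95. On the other side, CCL2 fell by 2.51, CSF1 by 1.04 and TNFAIP2 by 0.52 on the log2 scale. The list's median was 0.98 (camera, BH-adjusted p = 5.06e-06; adjusted p = 0.109 with an estimated correlation). Of 32 interferon response genes 14 rose and 1, IFI27, fell (15 and 3 adjusted over the list alone). Their median was 0.77 (camera, BH-adjusted p = 6.18e-05; adjusted p = 0.338 with an estimated correlation). The chemokine gene CXCL11 had 0 counts in DMSO and 180 over the treated libraries, at least 60.1-fold higher (edgeR QL, BH-adjusted p = 0.000233). CXCL10 rose from 0.178 to 4.26 CPM (4.55 ± 0.47, adjusted p = 2.06e-05) and IFIT2 by 3.82 on the log2 scale. IFNB1 itself had 0 counts in the 6 PEO1 libraries. Of 17 replication-dependent histone genes 10 rose and 0 fell (10 and 0 adjusted over the list alone; 1 lower at an unadjusted p under 0.05, by DESeq2 and by limma-voom). Among them were HIST1H2BK (chromosome 6, 27138293 to 27146858; 4.80 ± 0.411 to 73.5 ± 16.9 CPM, 3.93 ± 0.24) and HIST1H4H (3.70 ± 0.42). The histone median was 2.24 (camera, BH-adjusted p = 3.09e-06; adjusted p = 0.109 with an estimated correlation).

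Of 28 p53 targets 12 rose and 1, PLK2, fell in PEO1 (14 and 2 adjusted over the list alone). They were led by CDKN1A (6.74 ± 1.30 to 52.6 ± 11.5 CPM, 2.96 ± 0.23, edgeR QL, BH-adjusted p = 2.53e-06) and GADD45A (53.9 ± 2.94 to 332 ± 55.4 CPM, 2.62 ± 0.17, adjusted p = 3.64e-07). Their median was 0.48 (camera, BH-adjusted p = 0.00420; adjusted p = 0.109 with an estimated correlation). Of 23 cholesterol synthesis genes 11 were lower and 0 higher (11 and 0 adjusted over the list alone; 1 higher at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom). Their median was −0.46 (camera, BH-adjusted p = 2.27e-05; adjusted p = 0.0800 with an estimated correlation). MVD, a decarboxylase gene of the mevalonate pathway, fell from 12.6 ± 0.808 to 5.37 ± 0.812 CPM (−1.23 ± 0.28, edgeR QL, BH-adjusted p = 0.00527). Of 28 epithelial genes 12 fell and 1, OVOL1, rose (13 and 1 adjusted over the list alone). Their median was −0.48 (camera, BH-adjusted p = 0.000291; adjusted p = 0.0800 with an estimated correlation). The keratin gene KRT19 (chromosome 17, 41523617 to 41528389) fell from 715 ± 51.1 to 205 ± 27.2 CPM (−1.80 ± 0.21, adjusted p = 4.37e-05). The desmosome gene PKP3 fell by 1.39 on the log2 scale (adjusted p = 0.000516), KRT8 by 1.10 and KRT7 by 1.07.

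Other core lists in PEO1 held calls in both directions and did not pass camera. Of 41 E2F and replication genes 5 rose and 15 fell (5 and 16 adjusted over the list alone). The polymerase gene POLD1 was at −1.55 ± 0.23 (edgeR QL, BH-adjusted p = 0.000365), the ligase gene LIG1 at −1.17 ± 0.15 (adjusted p = 9.05e-05) and E2F7 higher by 1.04. The list's median was −0.25 (camera, BH-adjusted p = 0.0671, or 0.0267 with the length and GC correction). Of 35 G2/M and mitosis genes 2 rose and 8 fell, over all genes and adjusted over the list alone (median −0.11, camera, BH-adjusted p = 0.263, or 0.00104 and lower with the correction). The mitotic kinase gene PLK1 fell from 175 ± 1.34 to 89.3 ± 7.60 CPM (−0.97 ± 0.12, adjusted p = 6.13e-05). CENPE, a kinetochore motor gene, was at 0.81 ± 0.25 (adjusted p = 0.0278), which the correction took to 0.33 (adjusted p = 0.0834). Of 22 checkpoint genes 4 rose and 4 fell, also adjusted over the list alone (camera, BH-adjusted p = 0.943). ATR, the kinase upstream of CHK1, rose by 0.85 ± 0.24 (adjusted p = 0.0183), CHEK2 fell by 0.49 (adjusted p = 0.0488, not called without the A libraries or without a filter) and CDC25A rose by 0.56 ± 0.13 (adjusted p = 0.00628). PKMYT1, an inhibitory kinase of CDK1, fell by 1.02 (adjusted p = 0.0325), or −0.43 with the correction (adjusted p = 0.171). CHEK1 was at −0.17 ± 0.12 (adjusted p = 0.285), or −0.47 with the correction (adjusted p = 0.0414). WEE1 was at −0.02 ± 0.16 (adjusted p = 0.955), or −0.39 with the block and the correction (adjusted p = 0.00363).

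Of 35 homologous recombination and Fanconi anemia genes in PEO1, 2 rose and 7 fell, over all genes and adjusted over the list alone (median −0.10, camera, BH-adjusted p = 0.582). The risers were the recombination mediator gene BRCA2 (4.91 ± 2.22 to 18.1 ± 2.04 CPM, 1.88 ± 0.41, edgeR QL, BH-adjusted p = 0.00389) and the helicase gene FANCM (0.92 ± 0.27, adjusted p = 0.0204). FANCA fell by 0.66 on the log2 scale. Of 26 apoptosis genes 8 rose and 5 fell (the same numbers adjusted over the list alone; camera, BH-adjusted p = 0.378). The cytochrome c gene CYCS was at 1.15 ± 0.13 (adjusted p = 4.61e-05), MCL1 at 0.94 and the death ligand gene TNFSF10 at −1.48 ± 0.43 (adjusted p = 0.0188). Of 27 ATF4 and unfolded protein response genes 9 rose and 3 fell (9 and 6 adjusted over the list alone; camera, BH-adjusted p = 0.263). PPP1R15A rose from 59.2 ± 10.9 to 447 ± 64.2 CPM (2.92 ± 0.17, adjusted p = 2.01e-07) and the stress sensor gene ERN1 by 2.49 ± 0.49 (adjusted p = 0.00209). Of 30 transition and matrix genes 4 rose and 8 fell, also adjusted over the list alone (camera, BH-adjusted p = 0.197). The intermediate filament gene VIM was at −1.63 ± 0.20 (adjusted p = 8.17e-05), SNAI1 at 1.48 and SPARC at −1.29. The cyclin E1 gene CCNE1 fell by 0.55 (adjusted p = 0.0152), and MKI67 was at 0.28 ± 0.18 (adjusted p = 0.263).

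The PEO1 count was 7446 with the replicate block (3746 higher and 3700 lower), 5025 with the length and GC correction (2002 higher and 3023 lower, 3224 of the 4249 kept), 7266 with both (2826 and 4440), 2319 at an adjusted p under 0.01 and 1087 against a 1.5-fold minimum, and the list calls are limited in that other splits of the 6 libraries gave up to 11 of them against 7 here. Without any 1 PEO1 library the count was 3011 to 3361, with more lower than higher each time (1358 higher and 1788 lower without DMSO A, 1397 and 1867 without DMSO B, 1422 and 1872 without DMSO C, 1508 and 1853 without prexasertib A, 1376 and 1635 without prexasertib B, 1468 and 1887 without prexasertib C). Of the 41 named genes called, 37 stayed called without DMSO A (not ATR, CENPE, FANCM and CHEK2), 36 without DMSO B (not ATR, CENPE, FANCM, CHEK2 and CDC25A), 38 without DMSO C (not PKMYT1, CENPE and CDC25A), 37 without prexasertib A (not PKMYT1, CENPE, FANCM and CHEK2), 35 without prexasertib B (not PKMYT1, ATR, CENPE, FANCM, TNFSF10 and CHEK2) and 39 without prexasertib C (not ATR and FANCM).

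**Figure D1:**
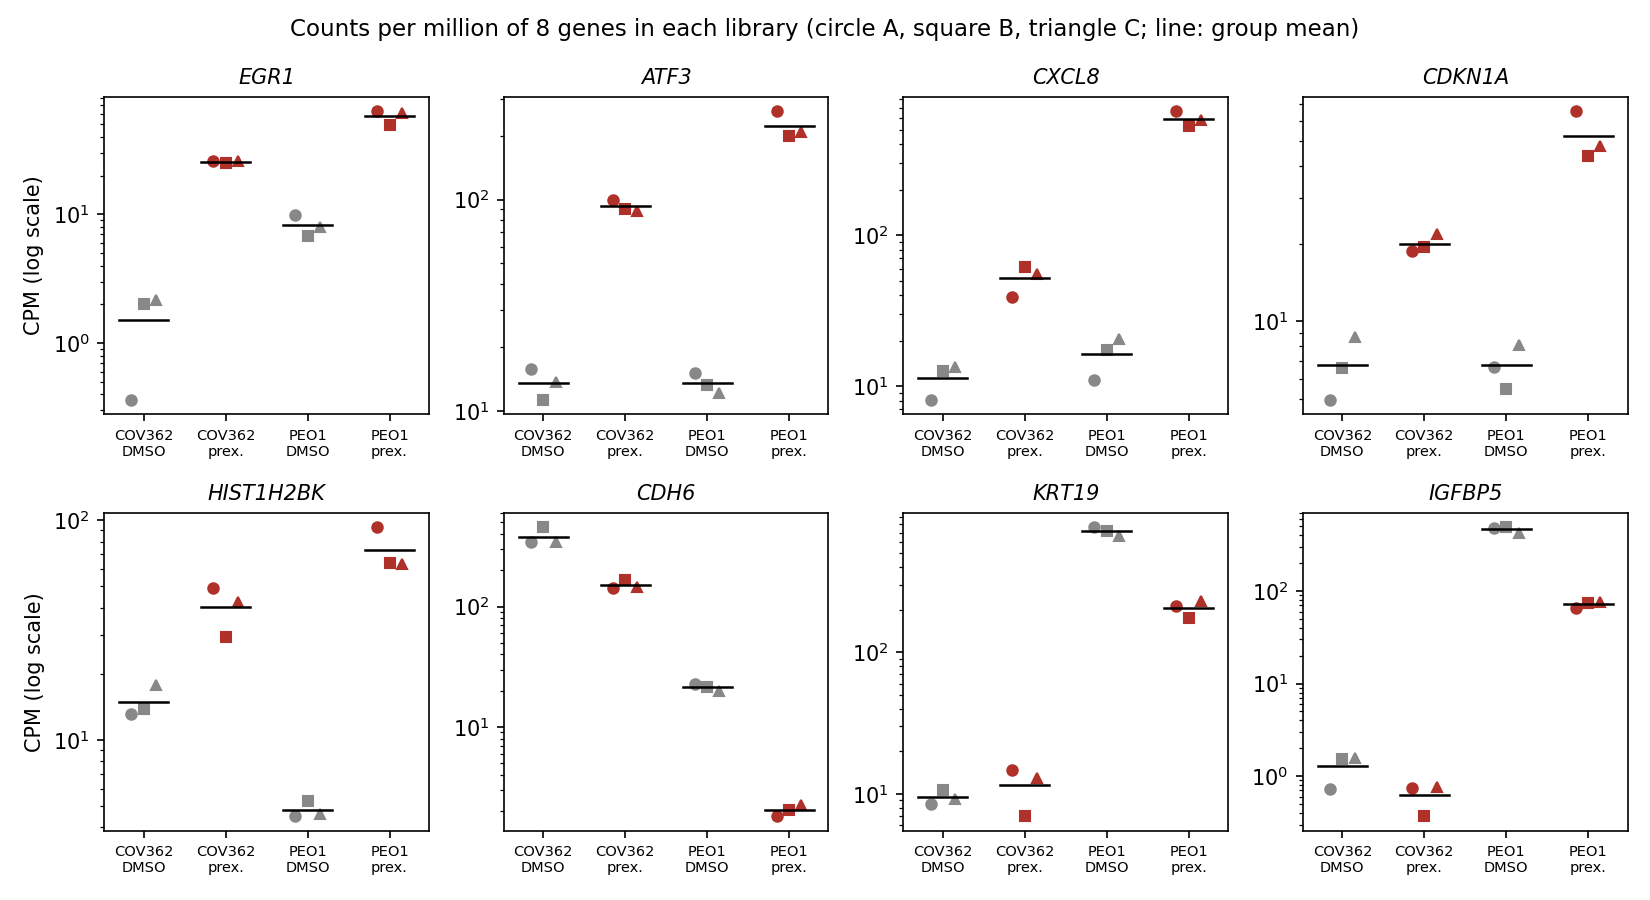
CPM on a log axis for EGR1, ATF3, CXCL8, CDKN1A, HIST1H2BK, CDH6, KRT19 and IGFBP5 in each library of the 4 groups, with circles for replicate A, squares for B and triangles for C. Horizontal lines give group means of 3 libraries.

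Where the changes differed between the lines, the larger one was mostly in PEO1, with the same sign in about as many genes as the opposite one. CXCL8 rose by 2.997 ± 0.34 more on the log2 scale in PEO1 than in COV362 (edgeR QL interaction, BH-adjusted p = 0.000458), ATF3 by 1.27 ± 0.22 more (adjusted p = 0.00681) and HIST1H2BK by 2.51 more (adjusted p = 0.000915). CDH6 fell by 2.06 more (adjusted p = 0.000295). Among genes with a mean of at least 5 CPM over the 12 libraries, the 5 highest called differences included PPARGC1A, a coactivator of mitochondrial biogenesis (chromosome 4, 23792021 to 23890077), which went from 9.82 to 4.60 CPM in COV362 and from 0.237 to 6.66 in PEO1 (5.79 ± 0.70, adjusted p = 0.000857). Most of the other highest and lowest were in genes silent in DMSO in 1 line. TMEM100, the exchange factor gene PREX1, the glutathione transferase gene GSTM3 and LPCAT2 had 0 counts in PEO1 DMSO and 16, 15, 17 and 9 over the treated libraries. They were at least 5.35-fold, 5.01-fold, 5.68-fold and 3.01-fold higher. The natriuretic peptide receptor gene NPR3, the connexin gene GJB5 and the calretinin gene CALB2 had 0 in COV362 DMSO and 21, 9 and 7 in the treated libraries. They were at least 6.45-fold, 2.77-fold and 2.15-fold higher and differed the other way. The rise within the line was not called for TMEM100 (adjusted p = 0.0800), GJB5 (adjusted p = 0.181) and CALB2 (adjusted p = 0.210). The called differences of all 7 had p-values of 0.0402 (TMEM100), 0.00738 (PREX1), 0.00498 (GSTM3), 0.0402 (LPCAT2), 0.00861 (NPR3), 0.0446 (GJB5) and 0.0461 (CALB2). The stem cell receptor gene LGR6 (−3.91 ± 0.73, adjusted p = 0.00997; 28.2 to 17.8 CPM in COV362 and 2.02 to 0.0788 in PEO1) and the flippase gene ATP10A (−3.61 ± 1.002, adjusted p = 0.0492; 43.4 to 11.2 CPM in PEO1) had the other lowest values. Called in opposite directions were EHF (−1.37 in COV362 and 1.02 in PEO1; difference 2.38 ± 0.29, adjusted p = 0.000915) and the transcription factor gene SOX4 (−0.73 and 0.52; 1.25 ± 0.21, adjusted p = 0.00555). So were the lipoprotein receptor gene LSR (1.32 and −0.78; −2.10 ± 0.33, adjusted p = 0.00424) and NPR3. FHL2, a LIM domain gene named here after its values were seen, was the fifth such gene (0.88 and −0.49; −1.37 ± 0.19, adjusted p = 0.00205).

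The interaction test called 885 genes, 455 with a higher and 430 with a lower value in PEO1. In 831 the absolute change was larger in PEO1, and in 451 the fitted changes had the same sign in both lines. By their calls in each line, 810 were called in PEO1 alone, 8 in COV362 alone, 26 in both the same way, 5 in both the opposite way and 36 in neither. Cholesterol synthesis genes were lower in PEO1 relative to COV362 (4 of 23 called lower, 5 adjusted over the list alone; median −0.46, camera, BH-adjusted p = 0.000365; adjusted p = 0.132 with an estimated correlation). So were epithelial genes (5 of 28 called lower, 7 adjusted over the list alone; median −0.55, camera, BH-adjusted p = 0.0233; 0.0715 without COV362 prexasertib B, 0.0553 without COV362 prexasertib C and 0.169 with the length and GC correction; adjusted p = 0.316 with an estimated correlation). No difference was called by camera for p53 targets (5 higher and 0 lower, BH-adjusted p = 0.0846, or 0.0224 with the length and GC correction), AP-1 genes (6 and 0; 0.185, or 0.0150 with the correction), interferon response genes (9 and 2; 0.185) or histone genes (1 and 0; 0.351). The G2/M list, with 0 higher and 3 lower, was lower in PEO1 with the correction (0.00056), and hypoxia and glycolysis genes with the block (0.0268, without it 0.0846, and 0.917 with the block and an estimated correlation). Without the A libraries the hypoxia list (0.0149) and the transition and matrix list (0.0408) also passed.

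The count of differences was 4906 with the replicate block (2586 higher and 2320 lower, all 885 kept) and 3602 with block and length and GC correction (1334 higher and 2268 lower, 784 kept). It was 328 to 591 without any 1 PEO1 library (DMSO A 328, B 419, C 388; prexasertib A 406, B 353), 390 and 465 without COV362 DMSO B and C, 1756 and 379 without COV362 prexasertib B and C, 1925 by DESeq2, 928 with upper-quartile scaling (382 higher and 546 lower), 1090 with the length and GC correction (449 and 641, 573 kept), 157 at an adjusted p under 0.01 and 83 against a 1.5-fold minimum. Of the 13 named differences called, TMEM100 and CALB2 were lost with the correction (adjusted p = 0.0757 and 0.0573), TMEM100, LPCAT2, GJB5, CALB2 and ATP10A with limma-voom, and TMEM100 and LPCAT2 without the A libraries. Without any 1 library between 8 and 12 held, the losses being among the same 5.

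**Figure D2:**
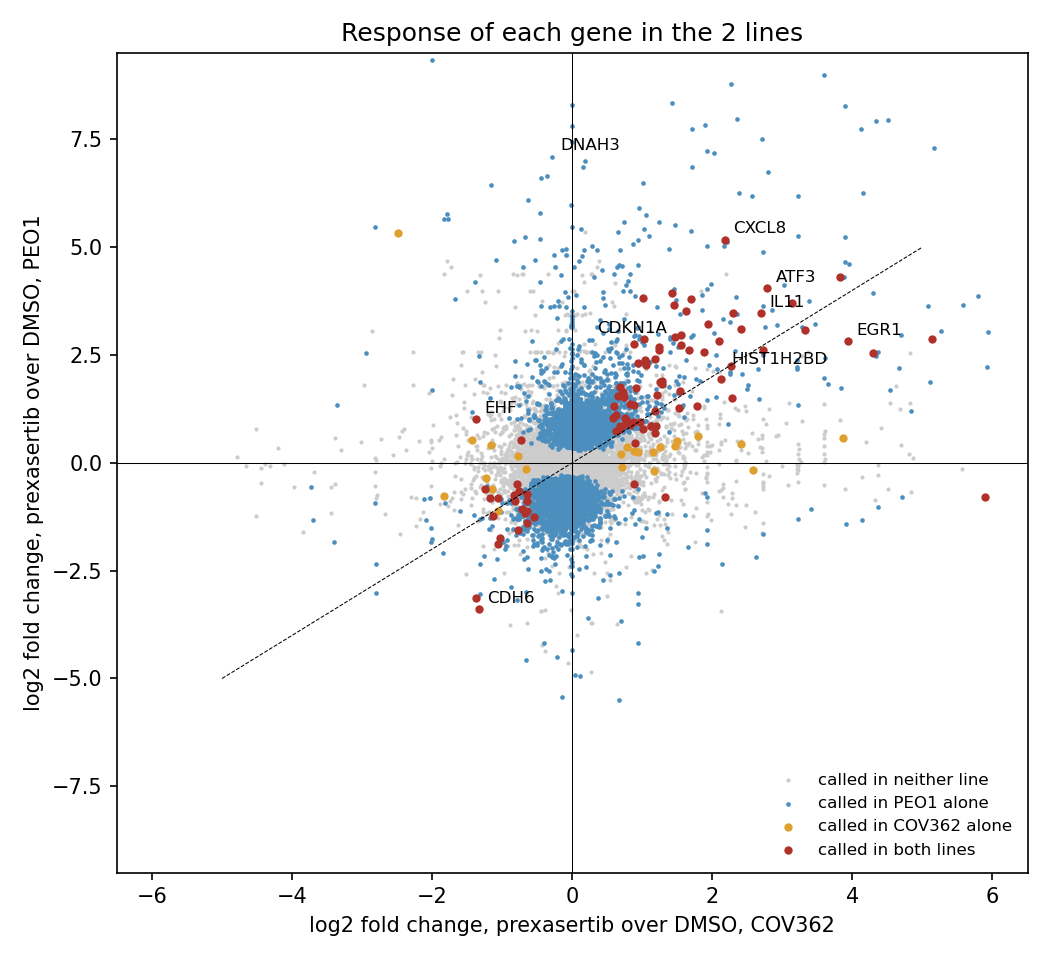
Log2 fold change with prexasertib in COV362 (horizontal) and PEO1 (vertical) for 14496 tested genes, 2 further genes lying outside the axes. Red marks genes called in both lines, blue in PEO1 alone, orange in COV362 alone and grey in neither, and the dashed line marks equal change.

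The genes that changed in COV362 mostly changed in PEO1 too. Of 120 genes called in COV362, 92 were called the same way in PEO1. Of these 71 were higher, where 13.0 would be expected from the 2 counts if calls were independent, and 21 lower, where 4.66 would be. EGR1, ATF3, CXCL8, CDKN1A, GADD45A, PPP1R15A and CDH6 are among them. Another 3 and 2 genes were called in opposite directions. Independence of the calls does not hold by design, because both comparisons used the same fit and shared its spread estimate for each gene. A gene with a low spread is thus more easily called in both lines, and the expected counts are only a rough reference. How much of the excess this accounts for was not tested. Only the separate fits given below do not share that estimate. Of the 88 COV362 risers 82 had the same sign in PEO1, and 53 had the larger change there. Of the 32 that fell, 26 had the same sign in PEO1, and 16 had the larger fall there. Across all tested genes, which are not independent replicates, the log2 fold changes of the lines correlated at r = 0.256 and rho = 0.227. The shared count was 348 by DESeq2, 1095 with the block, 305 with the length and GC correction, 234 without the A libraries, 9 from separate fits, 30 and 52 without COV362 DMSO B and C and 25 without COV362 prexasertib C. With the block 544 were higher where 215 would be expected, and 551 lower where 292 would be, a smaller excess in proportion. By DESeq2 these were 213 against 48.2 and 135 against 44.0, and from separate fits 8 against 1.83 and 1 against 0.46.

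**Figure D3:**
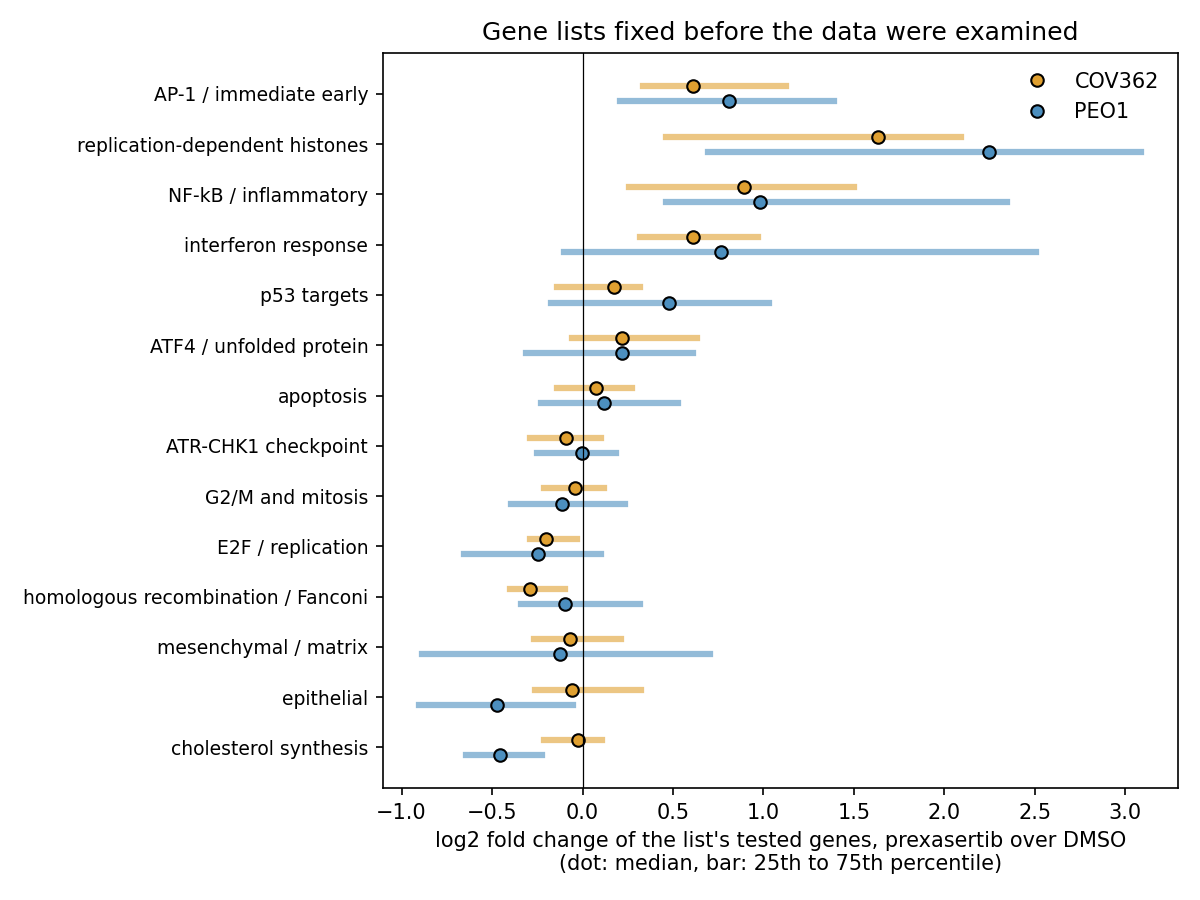
Median log2 fold change with prexasertib over the tested members of 14 gene lists, in orange for COV362 and in blue for PEO1. Bars run from the 25th to the 75th percentile of the members.

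In DMSO, some genes were expressed in 1 line and had no counts in the other. The kallikrein gene KLK5, the calprotectin gene S100A9 and the cornified envelope gene IVL had 0 counts in COV362 DMSO and 225, 112 and 105 CPM in PEO1 DMSO. They were at least 3114-fold, 1543-fold and 1464-fold higher. The matrix metalloproteinase gene MMP2, CDKN2A, which encodes the inhibitor p16, and TMEM100 had 0 counts in PEO1 DMSO and 245, 105 and 90.6 CPM in COV362 DMSO. They were at least 4189-fold, 1664-fold and 1588-fold higher (edgeR QL, BH-adjusted p from 1.50e-10 to 2.35e-07 over the 6 genes). In total 8361 genes (57.7% of those tested) differed, 4216 higher in PEO1 and 4145 higher in COV362. Of these 2615 and 2482 differed at least 2-fold, and 5258 passed a 1.5-fold minimum. Upper-quartile scaling moved the median of all genes to −0.11 on the log2 scale, with 8466 called (3809 higher and 4657 lower). Deviations of DMSO libraries with the same letter correlated between the lines at 0.35, 0.16 and 0.15 for A, B and C. With the letter as a block 9669 genes were called (4854 higher and 4815 lower), and 8279 of the 8361 were kept.

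Of 13 markers of the ovarian lineage, 12 were above 1 CPM in at least 1 group. PAX8, a transcription factor of Müllerian epithelium, was at 103 CPM in COV362 DMSO and 144 in PEO1 DMSO. Several others were high in 1 line only. MECOM was at 93.6 CPM in COV362 DMSO and 0.41 in PEO1 DMSO, where SOX17, EMX2 and FOLR1 were at 0. KLK10 was at 0.20 in COV362 DMSO and 37.5 in PEO1 DMSO. Values for other cell types are means of the highest of the 4 groups. Of other cell types, 3 of 12 immune markers (CD68 53.3 and CD14 4.27 CPM), 5 of 11 fibroblast markers (THY1 248 and COL1A1 6.18 CPM), 5 of 8 endothelial markers (CDH5 73.9 and KDR 7.32 CPM) and 0 of 6 erythroid markers (HBB highest at 0.0970 CPM) passed that level. In PEO1, 1 of 12 tested ovarian lineage genes rose and 4 fell (1 and 5 adjusted over the list alone; camera, BH-adjusted p = 0.263), among them WT1 by 1.06 and PAX8 by 0.57 on the log2 scale.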

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

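The tests of exon length and GC content, of reads shared between histone genes, of S phase and of relabellings within letters were chosen only after the result was seen, and the other tests in this part before. Each result of the next paragraph was picked out because the change with prexasertib differed between the lines by the interaction test (edgeR QL for genes and camera for lists, BH-adjusted p under 0.05). The values of that paragraph are log2 changes in PEO1 minus those in COV362. The count of genes in each line and the rise of histone genes were picked out from the tests within each line.

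Single inflammatory, immediate early and interferon genes differed upward in PEO1, although camera called no difference for their lists (BH-adjusted p = 0.846, 0.185 and 0.185): CXCL8 by 2.997, CXCL10 by 3.84, CCL5 by 4.34, FOS by 2.09 and ATF3 by 1.27. In these lists 3, 6 and 9 members were called higher and 2, 0 and 2 lower. The fitted 6.53 for CXCL11 and 7.38 for DNAH3 rest on a DMSO group at or near 0 counts. Stress and p53 genes differed by 1.41 (CDKN1A), 1.39 (GADD45A), 1.45 (PPP1R15A), 0.92 (MAP1LC3B) and 0.83 (CYCS), the histone gene HIST1H2BK by 2.51, MAOA by 4.84 and RAET1L by 4.05. Cell cycle and repair genes went apart in both directions, with CDC20 at −1.24, PLK1 at −1.03, POLD1 at −1.22, LIG1 at −0.88, CDC25A at 0.73 and BRCA2 at 2.27. Genes of adhesion, matrix, filaments and keratins in this set included CDH6 −2.06, BGN −2.36, KRT15 −2.40, IGFBP5 −1.56, TGM1 −2.55, VIM −1.60, KRT19 −2.08 and PKP3 −1.79, against TNC at 1.39 and MAP2 at 1.97. The sterol gene MVD was at −1.56, the cholesterol synthesis list had a median of −0.46 and the epithelial list one of −0.55. EHF (2.38), SOX4 (1.25) and LSR (−2.10) were called in opposite directions in the lines. Among genes with a mean of at least 5 CPM over the 12 libraries, the 5 highest and 5 lowest called differences were TMEM100 7.82, PREX1 5.91, PPARGC1A 5.79, GSTM3 5.30 and LPCAT2 5.24 on one side and NPR3 −6.68, GJB5 −5.50, CALB2 −5.39, LGR6 −3.91 and ATP10A −3.61 on the other. Those of TMEM100, PREX1, GSTM3, LPCAT2, NPR3, GJB5 and CALB2 depend on the prior count, since 1 group had 0 counts.

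Of the 10 splits of the 6 libraries of a comparison into 3 and 3, only the real one (1) called any gene in edgeR in COV362 (120, highest other 0), in PEO1 (4249, highest other 0) and between the DMSO groups (8361, highest other 0), which is too few splits for a share under 0.05. At an unadjusted p under 0.05 the other splits gave 235 to 4240 genes in COV362 against 1829 in the real one, 119 to 472 in PEO1 against 5949, and 44 to 927 between the DMSO groups against 8958. The COV362 split with 4240 set DMSO A, prexasertib A and prexasertib C against the rest, and the one with 3146 set DMSO A, DMSO C and prexasertib A against the rest, which points to a structure by replicate letter. Among the 4 COV362 splits that part all 3 letters, the real one alone called genes, 120 against 0 and, with the block, 1977 against 0. For gene lists, the real split in COV362 gave 12 (highest other 7; 1 of 10 as large) and in PEO1 7 (highest other 11; 3 of 10 as large), again too few splits for a share under 0.05.

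For the difference in response, 5 of 100 relabellings of the treatment within the lines called as many genes as the real 885 (highest other 2031). These mixed letters and used no block. As many lists as the real 2 were called by 72 of 100 (highest other 10). Neither share can decide on chance, which is thus not excluded for either count. Relabellings that kept the PEO1 groups still held the PEO1 drug effect, and those that broke them moved it into the spread. The relabellings that reached 885 were 4 of the 6 that kept the PEO1 groups and mixed those of COV362. Of the 93 that broke the PEO1 groups 0 called as many by edgeR, with a highest count of 0 called and of 3463 at an unadjusted p under 0.05. Of all 32 relabellings within letters, the real one included, 6 called as many genes without the block and 24 as many lists. With the block 2 called as many genes as the real 4906 and 23 as many lists, and the same limit leaves chance open here too. The other one of the 2 (6244) reversed COV362 as a whole, while the 6 that kept the PEO1 groups and mixed those of COV362 called at most 4032.

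Fewer genes were called in COV362 (120) than in PEO1 (4249). Lower depth was argued against: with each PEO1 library thinned to its COV362 counterpart, at least 4179 genes were still called over 5 draws. Noise alone was argued against too, because the covariance of log2 changes between different letters, which holds no noise of single libraries, was 0.493 to 0.572 in PEO1 and 0.0971 to 0.110 in COV362, the lowest of the first being 4.50 times the highest of the second. A trend with exon length and GC was argued against as the whole cause of the PEO1 calls, since 75.9% of them (3224 of 4249) kept call and direction after its removal. Even so, the log2 changes correlated with GC across genes at rho = −0.41 in PEO1 and −0.50 in the difference between the lines. In COV362 rho was 0.19 with GC, −0.25 with exon length and −0.33 with the genomic span of the gene. The correction did not model span, and after it rho with span was still −0.15 in COV362. In PEO1 rho with span was 0.03 before and −0.10 after the correction. Of the 885 called differences 573 were kept after the removal. The covariances above were computed without it. These covariances are consistent with smaller drug effects in COV362, and why they would be smaller was not tested.

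Replication-dependent histone genes had higher counts with prexasertib in both lines, with medians of 1.63 ± 0.48 in COV362 and 2.24 ± 0.78 in PEO1 (bootstrap SE). More RNA without a poly(A) tail in the treated libraries was argued against only by short RNAs as a set: 94 of that kind had medians of 0.24 ± 0.09 and −0.06 ± 0.10. In COV362 the longer ones were at 0.98 (RPPH1), 0.79 (RN7SK), 0.68 (RN7SL2), 0.36 (RMRP) and −0.08 (RN7SL1), with none called. In PEO1 RN7SK rose by 1.74 ± 0.50, while RN7SL2 was at 0.04, RMRP at −0.08, RPPH1 at −0.48 and RN7SL1 at −0.63. For longer RNAs the explanation stays open. Reads moving among the 17 tested histone genes of the list were argued against by their summed CPM. Its lowest treated library was at least 2.43 times the highest DMSO library in each line. This sum cannot speak to reads moving in from histone genes outside the list or below the filter. For more cells in S phase the E2F and replication list was examined, and its median did not rise. It was −0.20 ± 0.03 in COV362, with 0 members called, and −0.25 ± 0.13 in PEO1, with 5 members higher and 15 lower. These errors, taken over genes, hold no spread between libraries, and transcript levels do not count cells in S phase. That explanation thus stays open in both lines. A candidate explanation is more polyadenylated histone transcripts, as in cells leaving the cycle, which a count table cannot test.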

How the results depend on the processing

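The length and GC correction, the same with the replicate block, the block with an estimated correlation, and leaving out the A libraries were chosen only after the result was seen. No named gene that was called and no called list reversed its direction, which was not counted for the other genes, but uncalled ones did: with the length and GC correction MKI67 in COV362 went from −0.01 to 0.12 and the median of its ribosomal protein list from 0.07 to −0.05, and with the block its epithelial list turned higher. Of the values for named genes under the alternatives other than leaving out 1 library, 1167 stayed on their side of the threshold, 87 lost and 34 gained a call, and for called lists 127 stayed and 41 lost it, in all but 4 of these with the estimated correlation. Unless said otherwise, the cause was not tested.

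The replicate block gave 1977 genes in COV362, 7446 in PEO1, where the letters were not taken as pairs (best match with the own letter for DMSO A and B and prexasertib A and C), 4906 in the difference and 1095 shared. It ended no call of a named gene or list. Besides the COV362 gains given above it gained MKI67 (0.0128) and the E2F list (0.0449, but 0.313 with an estimated correlation as well) in PEO1 and the hypoxia list in the difference. In COV362 it also gained the YAP, NRF2 and ribosomal protein lists (camera, BH-adjusted p = 0.0152, 0.00407 and 0.0170). With an estimated correlation as well these were at 0.227, 0.227 and 0.686. It changed no other call of a list, or of a gene that the rule took and that is reported here. With the length and GC correction the counts were 410 in COV362 and 305 shared, with 4 lists in the difference, and with block and correction together 2123, 7266 (PEO1), 3602 (difference), 1516 shared and 4 lists in the difference. Without the A libraries they were 330 in COV362 and 234 shared, with 4 lists in the difference. DESeq2 gave 533 in COV362, 1925 in the difference and 348 shared. The 6 libraries of a comparison alone gave 10 in COV362 and 9 shared, with fewer samples to estimate the spread.

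Stricter criteria gave fewer genes by construction: an adjusted p under 0.01 gave 35 in COV362, 2319 in PEO1 and 157 in the difference, a 1.5-fold minimum 16, 1087, 83 and, between the DMSO groups, 5258, and an absolute log2 fold change of at least 1 gave 48 shared genes. With an estimated correlation 5 lists were called in COV362, 0 in PEO1 and 0 in the difference, where camera with the preset value called 12, 7 and 2, and with the block as well 0, 0 and 0. Fry, which compares no list with other genes, called 16 in PEO1 and 4 in the difference. RLE scaling, no filter and a filter of 1 CPM moved no count by over 1.5 times.

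Without any 1 library the counts ran from 27 to 128 in COV362, from 3011 to 3361 in PEO1, from 328 to 1756 in the difference, from 7513 to 8129 between the DMSO groups and from 25 to 100 shared, and lists from 11 to 15, 7 to 8 and 1 to 4. Leaving out COV362 DMSO A, the smallest library (9390790 counts), gave a COV362 count of 128, with 94 of the 120 calls kept. Whether that library held the count down was not tested.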

Other observations

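The length and GC correction and the genes singled out outside the lists were chosen only after the result was seen. Some genes were nearly silent in DMSO (under 0.1 CPM) and called at 1 CPM or more with prexasertib: 2 in COV362 (RFPL4A from 0 to 1.25 CPM and MYPN from 0.0548 to 1.10) and 54 in PEO1. Those in PEO1 include SCN3A (0.0582 to 4.78 CPM), STC1 (0.0362 to 4.51), CD300LB (0 to 3.99), NPTX2 (0.0550 to 3.89), TNFRSF9 (0.0550 to 3.51) and SLAMF7 (0.0724 to 3.17). The opposite, from 1 CPM or more to under 0.1, was called for 0 genes in COV362 and 2 in PEO1. The host transcripts of small nucleolar RNAs SNHG1 (log2 0.91 in COV362, edgeR QL, BH-adjusted p = 0.0207; 1.72 in PEO1, 1.40e-05) and SNHG12 (1.54, 0.0234; 1.67, 0.000756) rose in both lines.

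Of the interferon genes, IFNL1 had 0 counts in PEO1 DMSO and 58 over the treated libraries, at least 19.4-fold higher, while IFNB1 had 0 in both PEO1 groups.

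The remaining lists in PEO1, apart from ribosomal proteins, held calls in both directions. Of 25 hypoxia and glycolysis genes 4 rose and 9 fell (4 and 9 adjusted over the list alone; camera, BH-adjusted p = 0.190), with SLC2A1 at −0.84 and ADM at 1.42. Of 16 YAP targets 4 rose and 6 fell (4 and 7 adjusted over the list alone; 0.617), with ANKRD1 at 3.76, and of 16 TGF-beta targets 4 and 6 (4 and 6; 0.620). The MHC class I list also holds proteasome genes and CD274, the gene of an immune checkpoint ligand. Of its 16 genes 4 rose and 4 fell (4 and 5; 0.685). HLA-E, CD274, HLA-B and B2M rose, and PSMB8, PSMB9, PSMB10 and TAPBP fell. Lysosome and autophagy genes had 7 and 4 of 23 (8 and 5; 0.191, or 0.0271 with the length and GC correction), NRF2 targets 3 and 3 of 18 (6 and 3; 0.582), MYC targets 3 and 2 of 22 (3 and 2; 0.692), end joining and translesion synthesis genes 3 and 4 of 22 (3 and 4; 0.772), Notch and Wnt targets 4 and 3 of 18 (4 and 3; 0.943), drug transport genes 2 and 2 of 11 (2 and 2; 0.692) and cytosolic DNA sensing genes 1 and 2 of 9 (1 and 2; 0.943). Of 34 ribosomal protein genes 0 were called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (camera, BH-adjusted p = 0.999).

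In COV362 the MHC class I and lysosome lists passed camera, and the others of these and the cholesterol list did not: hypoxia and glycolysis 0.309, TGF-beta targets 0.606, YAP targets 0.0702 (with the block 0.0152, lower, but 0.227 with an estimated correlation as well), NRF2 targets 0.0646 (with the block 0.00407, higher, but likewise 0.227), MYC targets 0.171, ribosomal proteins 0.303 (with the block 0.0170, higher, but 0.686 with an estimated correlation as well, and with a median of −0.05 after the length and GC correction), end joining 0.0969, drug transport 0.955, Notch and Wnt targets 0.331, cholesterol synthesis 0.303 and cytosolic DNA sensing 0.979. Without the A libraries, camera also passed YAP targets (lower, BH-adjusted p = 0.0258), NRF2 targets (higher, 0.0087), MYC targets (higher, 0.0140) and ribosomal proteins (higher, 0.0258). BHLHE40, RRP12 and IFI16, called in edgeR, rose. Median, mean and test differed in sign for 0 of the called lists and for 6, 9 and 8 of the others in COV362, PEO1 and the difference.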
